A study of Homo sapiens with 4 samples.

How the data were processed

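Messenger RNA levels were measured in HLE and HLF cells, lines of hepatocellular carcinoma, on 4 one-colour Agilent arrays. Each line was transfected with 30 pmol of a miR-199a-3p mimic or of a mimic negative control and harvested at 72 h, and 100 ng of total RNA was labelled with Cy3. The treatment protocol in the labels names a miR-196a-3p mimic where all other labels name miR-199a-3p. The groups follow the sample titles, and the seed comparison in the results addresses the conflict. Each of the 4 groups holds 1 array. The arrays lie on 1 slide, each at its own position, so that array position and group cannot be separated.

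Per the file headers, the scanner files were made with Agilent Feature Extraction 10.7.3.1 and hold a processed signal as an intensity, after background subtraction and spatial detrending within the array, with low signals replaced by a surrogate value. Mean spot signal and local background are deposited as intensity too, with no correction. Per the file headers, the remaining columns used are of another unit (other): flags of 0 or 1 for signals well above background, saturated spots and outlying spots. The deposited series table holds the same processed intensity, rounded: its values differ from those of the scanner files by at most 0.0072 on the log2 scale, with column medians of 17.8, 13.8, 14.9 and 12.7 in the order HLE control, HLE mimic, HLF control, HLF mimic. The values were not normalised between arrays.

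Each array has 62976 spots, of which 58717 are not controls, with 50599 distinct probes of 60 bases. Repeated spots were averaged after spots with an outlier flag were left out (402, 309, 331 and 368 spots in the same order). Of the probes, 31438 matched a gene of the reference table (28174 by transcript accession, 2618 by symbol, 593 by synonym and 53 by another accession) and 19161 did not. Positions are those the scanner files give for the probes on hg19. Which exon or untranslated region a probe lies in is not given. The 226 probes of Y-linked genes and XIST were left out. One probe stood for each gene, that with the highest mean log2 signal, and the text gives the mean of the other probes of some genes. Unless stated, these are probes well above background on at least 1 array of each line. Values are log2 of the processed signal minus the 75th percentile of the array. Genes well above background on at least 1 array of each line were tested, 17927 of 36217, and 13970 of these carry a symbol of the reference table.

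Mimic and control were compared over both lines with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with the line as a block, and HLF with HLE in the same fit. The fit had 1 residual degree of freedom, 2.70 prior degrees of freedom and a prior SD of 0.184. P-values were two-sided and adjusted by Benjamini-Hochberg over all tested genes, with a threshold of 0.05. Changes within a line and differences between the lines are values with no test. Leaving out a line leaves no residual degree of freedom and gives the values within the other line. Groups are too small for other splits of the arrays. The remaining steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.

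The comparisons, the 21 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Named over both lines were the 15 lowest and the 15 highest genes, ranked by the smaller of the 2 absolute log2 ratios with both of 1 sign. In each line, the 5 lowest and 5 highest ratios were named among probes well above background on the brighter array. For HLF against HLE the rule took 8 genes each way with the same sign under both treatments, and for the difference between the lines 5 genes each way. MET, MTOR, CD44 and YAP1 were always named, with 2 to 4 examples per list. Results of some genes that the rule takes are not reported here. Genes without a symbol were not named, and placeholder symbols starting with LOC counted as none. Each list's median was set beside 10000 random lists matched on mean signal in 20 bins. The lists were tested with camera in limma, with a preset correlation of 0.01 and with an estimated one, and with fry. The estimated correlation and its test rest on 1 residual degree of freedom, so that version had little power for any list.

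The planned search for seed matches in 3 prime untranslated regions could not be made, because no transcript sequence was available, and matches in coding regions were not run for the same reason. Matches to bases 2 to 8 of the microRNA, or to a 6-base part of these, were searched instead in the 60-base probe of each of 12646 protein-coding genes. Each kind was also searched with an A after it. This A was the same for every microRNA and was not matched to the microRNA's first base. That search, the scaling to E1A spike-in RNA, the removal of spots in clusters of outlying spots and the addition of 16 before the log in the model over both lines were chosen after seeing the data. The other alternatives were quantile normalization, a modelled background (normexp with an offset of 50) with quantile normalization, centring on the median, no filter on dim probes, only genes well above background on all 4 arrays, the mean of a gene's probes, the series table, no block, eBayes with a trend, and fold thresholds of 1.5 and 3. Scaling by the median shifted the median log2 ratio of all tested genes by -0.28 in HLE and -0.18 in HLF, spike-in scaling by -1.00 and -0.54, and leaving out the filter by 0.34 and 0.28.

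The fit was tested on simulated data, with gene variances drawn from the fitted prior and independent noise on each array. Shifts of whole arrays and clusters of outlying spots were not simulated, so the recovered shares need not hold for these arrays. With 200 changed genes, 0% of changes of 1 on the log2 scale, 5.97% of 2 and 86.6% of 3 were recovered, with 6 false calls. With 3000 changed genes these shares were 57.9%, 95.7% and 98.4%, with 124 false calls. Planted shifts of gene lists and of heptamers were recovered as well.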

Results

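Gene expression was measured on 4 one-colour arrays of 60-base probes. RNA came from HLE and HLF, established cell lines from hepatocellular carcinoma, 72 h after transfection with a synthetic mimic of the microRNA miR-199a-3p or with a negative-control mimic. The 4 groups, each line with control or mimic, held 1 array each, and all 4 arrays lay on 1 slide. The 75th percentile of the spot signals was 619 intensity units for HLE with control and 390 with mimic. For HLF it was 490 with control and 366 with mimic. Between 50.5% and 54.5% of the spots on an array were well above background, and none was saturated. Probes spotted 10 times on an array had a median SD of 0.07 to 0.08 on the log2 scale. Of 36217 genes and transcripts measured, 17927 were well above background on at least 1 array of each line and were tested. Changes are log2 ratios of mimic over control after each array was set to its 75th percentile, and "±" gives the SD of the 2 lines (n = 2). Values within a line have no replicate, and the number of arrays limits the precision of every value. Mimic and control were paired within each line, with the line as the block, and no group had replicate arrays because each holds 1 array.

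The first comparison asked which transcripts differed after the mimic in both lines. The ring finger gene RNF141 (NM_016422; probe on chromosome 11, 10533514 to 10533573, hg19) was 15.5-fold lower, with a log2 ratio of -3.95 ± 0.05. PON2, a paraoxonase (NM_000305; chromosome 7, 95034500 to 95034559), was 10.1-fold lower (log2 ratio -3.34 ± 0.08). NECTIN2, a cell adhesion protein of adherens junctions (NM_001042724; chromosome 19, 45392321 to 45392380), was 13.8-fold lower (log2 ratio -3.79 ± 0.23), while its other probe gave -0.38 in HLE and -0.42 in HLF. VAMP3, a vesicle fusion protein, was 9.11-fold lower (log2 ratio -3.19 ± 0.07) and its other probe gave -2.05 and -2.03. SNN was 11.7-fold lower, ARL6IP1, which shapes the endoplasmic reticulum, 6.97-fold, and NACC1, a transcriptional regulator, 8.78-fold. The RNA polymerase III subunit POLR3G was 9.25-fold lower, and its other probe gave -1.34 in HLE and -1.15 in HLF. The ubiquitin ligase RNF14 was 6.96-fold lower (log2 ratio -2.80 ± 0.15), with -3.16 and -2.87 by its other probe.

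Among the 15 genes chosen as lowest in both lines, the mimic signal of 6 was not well above background in at least 1 line, so that their change is a lower bound. Each bound is the brighter signal over the higher of the dim probe's own signal and the lowest well-above-background signal of its array. ITGB8, an integrin chain, was 6.37-fold lower in HLE and at least 6.25-fold lower in HLF. ELF3, an epithelial transcription factor, was at least 1.87-fold lower in HLE and at least 6.24-fold lower in HLF. SLC43A2, an amino acid transporter, was at least 3.46-fold and 6.28-fold lower in HLE and HLF. DEPP1 was at least 15.2-fold lower in HLE and 6.48-fold lower in HLF. VXN was 8.05-fold lower in HLE and at least 6.59-fold lower in HLF. The long non-coding RNA LINC01634 was 8.73-fold lower in HLE and at least 11.6-fold lower in HLF.

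The gene most increased in both lines was MMP3, the matrix-degrading protease stromelysin 1 (NM_002422; chromosome 11, 102706694 to 102706753). It was 53.3-fold higher in HLE and 211-fold higher in HLF, with a mean log2 ratio of 6.73 ± 1.40. FST, which encodes the activin-binding protein follistatin (NM_013409; chromosome 5, 52780837 to 52780896), was 13.1-fold higher (log2 ratio 3.71 ± 0.54). LOX, the enzyme that cross-links collagen and elastin (NM_002317; chromosome 5, 121405786 to 121405845), was 7.74-fold higher (log2 ratio 2.95 ± 0.12). SGIP1 was 8.20-fold higher (log2 ratio 3.04 ± 0.23), and its other probe gave 2.96 in HLE and 3.55 in HLF. The remaining 11 of the 15 were not well above background on a control array of at least 1 line. The antisense transcript STXBP5-AS1, whose probe is read from the strand opposite to STXBP5, was at least 26.8-fold higher in HLE and at least 8.55-fold higher in HLF. PLCE1-AS1, another antisense transcript, was at least 18.1-fold higher in HLE and 23.7-fold higher in HLF. SAMD3 was 20.4-fold higher in HLE and at least 3.68-fold higher in HLF. INSYN2B was 19.2-fold higher in HLE and at least 11.8-fold higher in HLF, and LINGO2 10.5-fold and at least 10.2-fold. The bounds of TRIML1 were 8.68-fold in HLE and 7.13-fold in HLF, and those of HCLS1, a blood-cell protein, 23.3-fold and 2.91-fold. The bounds of SERPINB2, a protease inhibitor, were 1.86-fold and 2.49-fold, and those of GDPD3 1.99-fold and 3.73-fold. SLC6A13, a GABA transporter, was at least 11.7-fold higher in HLE and 7.15-fold higher in HLF. DEFB103B, a defensin with near-identical copies so that the copy is uncertain, was at least 11.1-fold higher in HLE and 2.15-fold in HLF.

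By limma, 0 of 17927 genes passed an adjusted p of 0.05 for the mimic. The smallest adjusted p was 0.0542, and 1127 genes lay under 0.06. At an unadjusted p under 0.05 there were 5560 genes, 2453 lower and 3107 higher, where chance alone gives 896. The limma adjusted p of the 30 genes named above lay between 0.0542 and 0.0571. Of all tested genes, 642 were at least 2-fold lower in both lines and 700 at least 2-fold higher, against 77.4 and 124 for independent lists of the same lengths. These counts take ratios of dim probes as computed, and among genes well above background on all 4 arrays they were 478 and 516. A technical shift shared by the mimic arrays could also make the lists overlap. The excess over independent lists is thus not by itself a measure of the response to the mimic. The log2 ratios in HLE and HLF correlated across genes (Pearson r 0.649, Spearman rho 0.654), and no p-value is given because genes are not replicates. The limma p-values rest on 2 lines, with 1 residual degree of freedom and 2.70 prior degrees of freedom taken from the spread of all genes. They do not measure a spread of replicates within a line. The count of calls ranged from 0 to 6266 over other settings. Other scalings also changed the split: 52.2% of the genes at least 2-fold changed in both lines were higher, against 29.7% with median centring, 41.8% with a modelled background and quantile scaling, 63.5% with no filter on dim probes and 4.61% with scaling to spike-in RNA.

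**Figure D1:**
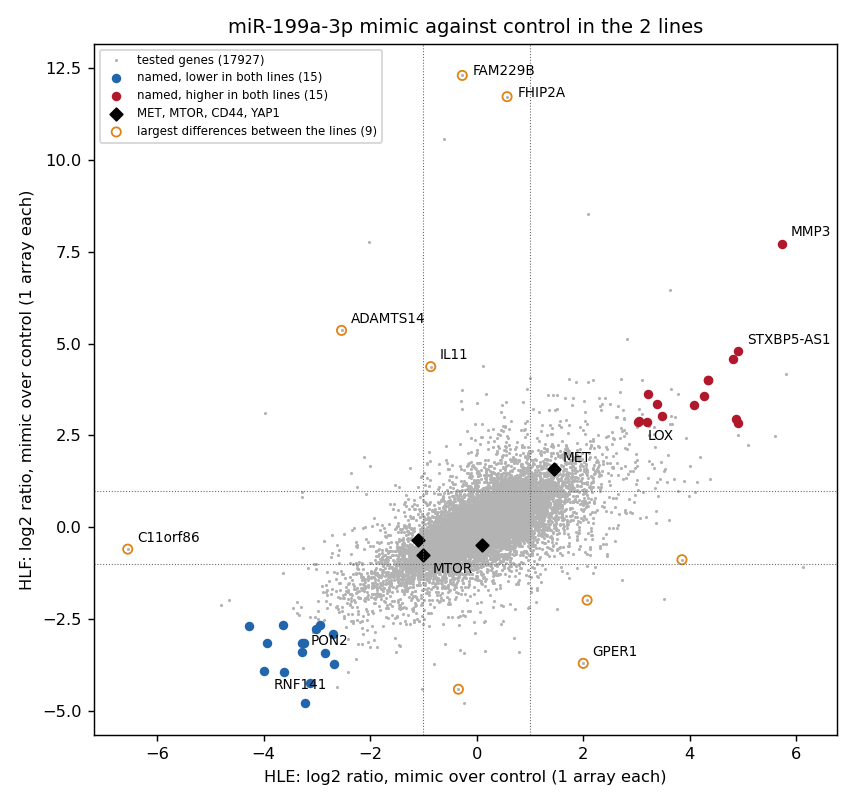
Log2 ratio of mimic over control in HLE (horizontal axis) and in HLF (vertical axis) for the 17927 tested genes, each point 1 gene from 1 array per group; dotted lines mark a 2-fold change. The 15 genes named as lower lie at the lower left and the 15 named as higher at the upper right with MMP3 at 5.73 and 7.72, while FAM229B (12.30 in HLF, -0.27 in HLE) and other open circles lie off this diagonal.

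Genes reported as miR-199a-3p targets were fixed as a list before the data were examined. Of the 17 tested members, 5 fell and 1 rose adjusted over the list alone, and 0 passed over all genes. Of all 17927 tested genes, 5560 had an unadjusted limma p under 0.05, so members of any list may pass over that list alone. Such counts, here and for the lists below, thus do not set a list apart from other genes. ITGA3, an integrin chain, fell 4.53-fold (log2 ratio -2.18 ± 0.25), and PAK4, a kinase of the actin cytoskeleton, fell 3.43-fold (log2 ratio -1.78 ± 0.48). MTOR, the growth kinase (NM_004958; chromosome 1, 11167492 to 11167551), fell 1.84-fold (log2 ratio -0.88 ± 0.18). ZHX1 and DNAJA4 fell by 0.86 and 0.78 on the log2 scale. MET, the receptor of hepatocyte growth factor (NM_000245; chromosome 7, 116438290 to 116438349), rose 2.86-fold (log2 ratio 1.52 ± 0.09). CD44, a hyaluronan receptor (NM_000610; chromosome 11, 35253812 to 35253871), had log2 ratios of -1.10 in HLE and -0.36 in HLF, and -0.04 and 0.14 by its other probe. YAP1, the effector of the Hippo pathway (NM_006106; chromosome 11, 102100584 to 102100643), had 0.10 in HLE and -0.48 in HLF. The median log2 ratio of the list was -0.21 in HLE and -0.36 in HLF, at percentiles 3.22 and 0.44 of 10000 random lists matched on expression. Its camera adjusted p, from the set test in limma with a preset correlation, was 0.0301, and the adjusted p was 0.956 with an estimated correlation. For this and every other list the estimated version rests on 1 residual degree of freedom and had little power. The preset-correlation p was 0.0566 with quantile normalization and to 0.0522 with spike-in scaling.

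Genes of focal adhesion and the actin cytoskeleton were lower as a group. Of 24 tested members, 17 were lower in both lines, and 5 fell adjusted over the list alone (0 over all genes): ITGB8, ITGA3, the adaptor PXN, the integrin chain ITGAV and the caveolar protein CAV1. PXN had a log2 ratio of -1.47 ± 0.32, but -0.13 in HLE and -0.01 in HLF by the mean of its 2 other probes. ITGAV had -1.09 ± 0.27 and CAV1 -1.01 ± 0.28. The list's median was -0.51 in HLE and -0.37 in HLF, at percentile 0 of random lists in each line. Its camera adjusted p was 0.00125, and the adjusted p was 0.956 with an estimated correlation.

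Genes of the unfolded protein and integrated stress responses were higher relative to other genes. Of 18 tested members, 13 were higher in both lines and 7 rose adjusted over the list alone (0 over all genes). PPP1R15A, a phosphatase subunit that restores translation, rose 3.22-fold (log2 ratio 1.69 ± 0.20). HERPUD1, a protein of endoplasmic reticulum degradation, rose 3.15-fold (1.66 ± 0.46), and the transcription factor CEBPB rose 2.53-fold (1.34 ± 0.25). TRIB3, XBP1, DNAJC3 and PDIA4 also rose. The chaperone HSPA5 had log2 ratios of 0.80 in HLE and 0.10 in HLF, DDIT3 had 1.27 and 0.00, and ATF3 had -0.39 and -0.91. The list's median was 0.77 in HLE and 0.53 in HLF, at percentile 100 in each line, but -0.24 and -0.01 with spike-in scaling, which left it 0.67 and 0.49 above the median of all genes. Its camera adjusted p was 0.0301, and the adjusted p was 0.956 with an estimated correlation. The preset-correlation p was 0.162 with no filter on dim probes and 0.0522 with spike-in scaling.

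Genes of cholesterol synthesis and uptake had a median of -0.38 in HLE and -0.13 in HLF, at percentiles 0.17 and 6.97. Of 17 tested, 10 were lower in both lines, and 0 passed adjusted over the list alone or over all genes. LSS, the lanosterol synthase, had a log2 ratio of -0.77 ± 0.22. The camera adjusted p was 0.0452, and the adjusted p was 0.956 with an estimated correlation. The preset-correlation p was 0.0767 with quantile normalization, 0.0533 with genes well above background on all arrays and 0.256 with spike-in scaling.

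The 17 other lists had camera adjusted p-values from 0.109 to 0.948. Of the 11 tested epithelial markers, 4 fell and 1 rose adjusted over the list alone (0 over all genes). JUP, the junction protein plakoglobin, fell 3.96-fold (log2 ratio -1.99 ± 0.12), the tight-junction protein OCLN fell 2.55-fold (-1.35 ± 0.54) and KRT7 fell 1.88-fold (-0.91 ± 0.21). KRT8 fell by 0.77 on the log2 scale, but the mean of its 2 other probes was 0.42 in HLE and 0.34 in HLF. CLDN1, another tight-junction protein, rose 6.66-fold (log2 ratio 2.73 ± 1.01). The list's median was -0.44 in HLE and -0.38 in HLF, or -0.17 and -0.38 with the dim member at its bound and -0.31 and -0.57 with it left out. By fry, which tests whether the genes of a list move on balance one way without comparing them with other genes, this was the only list past 0.05 (adjusted p 0.0134).

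Mesenchymal markers moved both ways: of 17 tested, 4 fell and 2 rose adjusted over the list alone (0 over all genes), with medians of 0.06 in HLE and -0.18 in HLF. S100A4, a calcium-binding protein, fell 4.35-fold (log2 ratio -2.12 ± 0.23), and the gelatinase MMP2 fell 2.18-fold. COL1A2, a collagen chain, was 2.81-fold lower in HLE and at least 1.54-fold lower in HLF. SNAI2, a transcriptional repressor, was 4.24-fold higher in HLE and at least 3.02-fold higher in HLF, and VIM had a log2 ratio of 0.25 ± 0.08. Of 22 tested genes of the extracellular matrix and its proteases, 3 rose and 1 fell adjusted over the list alone (0 over all genes). Among these, MMP3 and LOX rose and the urokinase PLAU fell (log2 ratio -0.97 ± 0.29). That list's medians were 0.15 in HLE and -0.15 in HLF.

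YAP and TEAD target genes had medians of -0.08 in HLE and 0.19 in HLF. Of 19 tested, 6 rose and 2 fell adjusted over the list alone (0 over all genes). The ectoenzyme NT5E rose 3.81-fold (log2 ratio 1.93 ± 0.34), GADD45A rose 2.71-fold (1.44 ± 0.11) and CCN2 rose 1.89-fold (0.92 ± 0.07), while CCN1 had -0.02 ± 0.07. LATS2, a kinase of the Hippo pathway, fell 2.26-fold (log2 ratio -1.18 ± 0.38). Of 18 tested Hippo pathway components, 0 passed adjusted over the list alone or over all genes, with medians of 0.09 and 0.22. Of 17 mTOR pathway components, 1 rose over the list alone (0 over all genes): SESN2, a stress-induced inhibitor of the pathway (2.83-fold, log2 ratios 1.74 in HLE and 1.26 in HLF), and the medians were -0.01 and 0.01. Of 20 genes of receptor tyrosine kinase and MAPK signalling, 1 rose over the list alone (0 over all genes), which was MET, and EGFR had a log2 ratio of 0.60 ± 0.24. Their medians were -0.05 in HLE and 0.07 in HLF.

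Cell-cycle lists lay near the median of all genes. None of 25 tested genes of DNA replication and G1/S passed over the list alone or over all genes, with medians of 0.07 in HLE and 0.17 in HLF. Of 20 mitosis genes, 1 fell over the list alone (0 over all genes): the kinase AURKA, 2.33-fold (log2 ratio -1.22 ± 0.01). The mitosis medians were 0.07 and -0.11, and the proliferation marker MKI67 had a log2 ratio of 0.81 ± 0.06. Of 20 p53 target genes, 4 fell and 3 rose over the list alone (0 over all genes), with medians of -0.09 and 0.07. TP53INP1 fell 5.48-fold (log2 ratio -2.45 ± 0.42) and MDM2, the p53 ubiquitin ligase, fell 2.05-fold, with BTG2 and RRM2B. CDKN1A, the p21 inhibitor of cyclin-dependent kinases, rose 2.56-fold (log2 ratio 1.35 ± 0.20), with GDF15 and SESN2.

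Among 14 tested genes of NF-kB signalling and inflammatory cytokines, 3 rose and 3 fell adjusted over the list alone (0 over all genes). IL1B was at least 10.8-fold higher in HLE and 2.02-fold in HLF, IL6 rose 2.78-fold (log2 ratio 1.47 ± 0.49) and the chemokine CXCL1 rose 2.63-fold (1.39 ± 0.32). BIRC3 fell 4.02-fold (log2 ratio -2.01 ± 1.12), NFKB2 1.94-fold, and NFKBIA, the NF-kB inhibitor, 1.96-fold. The list's medians were 0.27 and 0.41, and -0.73 and -0.13 with spike-in scaling. Of 18 type I interferon response genes, 2 fell and 1 rose over the list alone (0 over all genes), with medians of 0.38 in HLE and -0.03 in HLF. RIGI, a sensor of double-stranded RNA, fell 3.88-fold (log2 ratio -1.96 ± 0.36), IFIT1 fell 2.55-fold and IFI44 rose 2.26-fold. Of 17 hypoxia and glycolysis genes, HK2, a hexokinase, rose 3.80-fold (log2 ratio 1.92 ± 0.08) and ANKRD37 2.30-fold, while NDRG1 fell 3.03-fold and PFKFB3 1.88-fold over the list alone (0 over all genes). The medians were -0.05 and -0.07.

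Of 14 genes of the microRNA pathway, AGO2, the slicing Argonaute (log2 ratio 0.99 ± 0.07), and AGO3 rose and the Dicer partner PRKRA fell over the list alone (0 over all genes), with medians of -0.15 and -0.09. Only 3 of 20 hepatocyte genes were tested, with medians of -0.06 and -0.42. Of these, the fibrinogen chain FGB fell over the list alone (0 over all genes), 5.35-fold in HLE and at least 4.26-fold in HLF. Of 16 leukocyte and endothelial markers 6 were tested, and CD14 (log2 ratio -0.85 ± 0.35) and TEK fell over the list alone (0 over all genes). The medians of that list were -0.68 and -0.50, or -0.30 and -0.50 with dim members at their bounds. Of 12 housekeeping genes, YWHAZ fell over the list alone (0 over all genes) with -1.35 ± 0.05, and -0.22 and -0.63 by its other probe. GAPDH had -0.19 ± 0.08 and ACTB 0.28 ± 0.04. The housekeeping medians were 0.19 in HLE and 0.07 in HLF, but -0.10 and -0.11 with median centring and -0.82 and -0.47 with spike-in scaling.

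Of the 21 lists, 4 passed 0.05 by camera with the preset correlation and 0 with an estimated one. With 1 residual degree of freedom the estimated version could hardly pass any list, so it does not decide between them. A fry test for change in either direction passed for 5: the reported targets, YAP and TEAD targets, Hippo components, receptor tyrosine kinase signalling and the extracellular matrix. Median, mean and tests differed in sign for the YAP and TEAD, mTOR, receptor tyrosine kinase, p53, hypoxia, extracellular matrix and housekeeping lists. For the extracellular matrix list the median of the mean ratios was -0.13, the mean 0.39 and the camera direction down. Spike-in scaling and median centring move all lists alike, so that they change the sign of a list's median but not its distance from the median of all genes. Other settings change that distance too: for housekeeping genes it was 0.09 in HLE and 0.03 in HLF, but -0.11 and -0.13 with quantile normalization. In all, 10 tested genes belonged to more than 1 list, MET and ITGA3 among them.

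**Figure D2:**
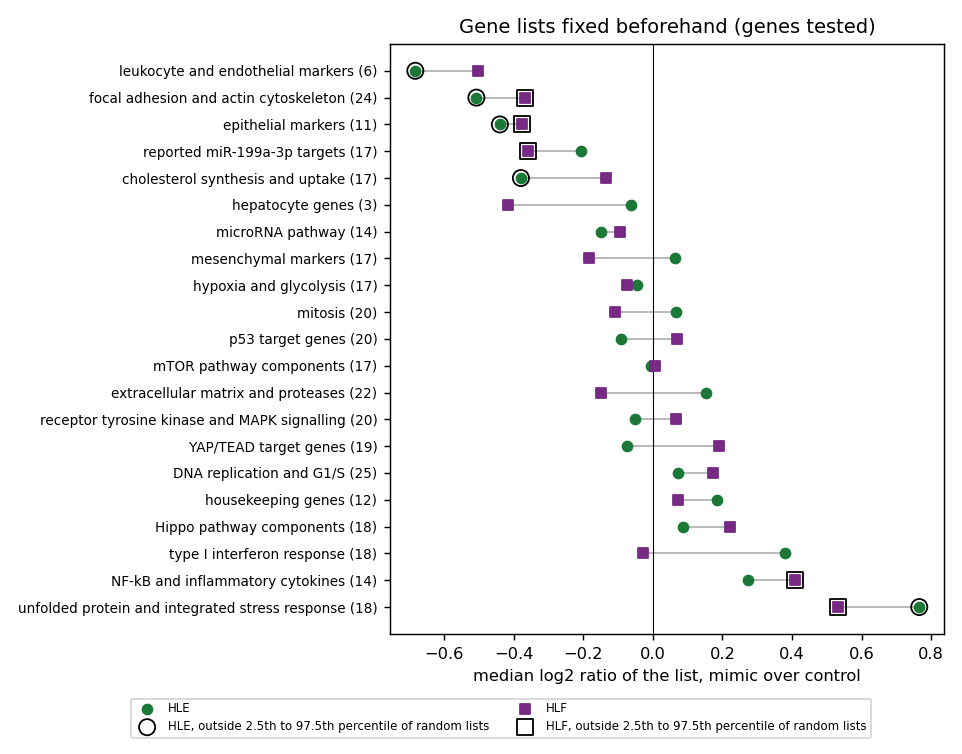
Median log2 ratio of mimic over control for each of 21 gene lists (tested members in brackets) in HLE (circles) and HLF (squares), each from 1 array per group; outlined points lie in the outer tails of 10000 random lists, at the percentiles in the legend. Focal adhesion genes lie at -0.51 and -0.37 and stress response genes at 0.77 and 0.53, and the latter fall to -0.24 and -0.01 with spike-in scaling.

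The labels name 2 different microRNAs, miR-199a-3p in most fields and miR-196a-3p in the treatment protocol, so genes were compared by the seed match carried in their own probe. In all, 13 genes held ACTACTGA, counted here as the 8-base match of miR-199a-3p: the match to bases 2 to 8, then an A. Of these 13 genes, 9 (69.2%) were at least 2-fold lower in both lines, against 4.15% of 12425 genes without a match. The median of these 13 genes minus that of genes without a match was -1.44 in HLE and -1.65 in HLF. NECTIN2 was the lowest of them, and DYNLT2B (log2 ratio -2.43 ± 0.52) and SLC49A4 (-2.23 ± 0.66) were among the next, named after their values were seen. The mimic signals of PPM1J and FGF7, which count among the 9, were not well above background in either line. Genes with the 7-base match ACTACTG (53 genes) had a difference of -0.62 in HLE and -0.58 in HLF. Those with CTACTGA, a 6-base match followed by an A (48 genes), had -0.65 and -0.55. Genes with any match, down to the 6 bases CTACTG (221 genes), had -0.28 and -0.22, below each of 10000 random sets matched on expression. These sets are nested: the 13 genes with the 8-base match count in each of them, so the differences are not separate support. Genes with the miR-196a-3p match TGTTGCC (72 genes) differed by -0.01 and -0.02, and those with the miR-199a-5p match ACACTGG (69 genes) by 0.01 and 0.00. Of 11013 heptamers, ACTACTG ranked 1 and CTACTGA ranked 2 from the lowest in each line. A probe covers 60 bases of a transcript, so genes without a match in the probe can hold one elsewhere.

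**Figure D3:**
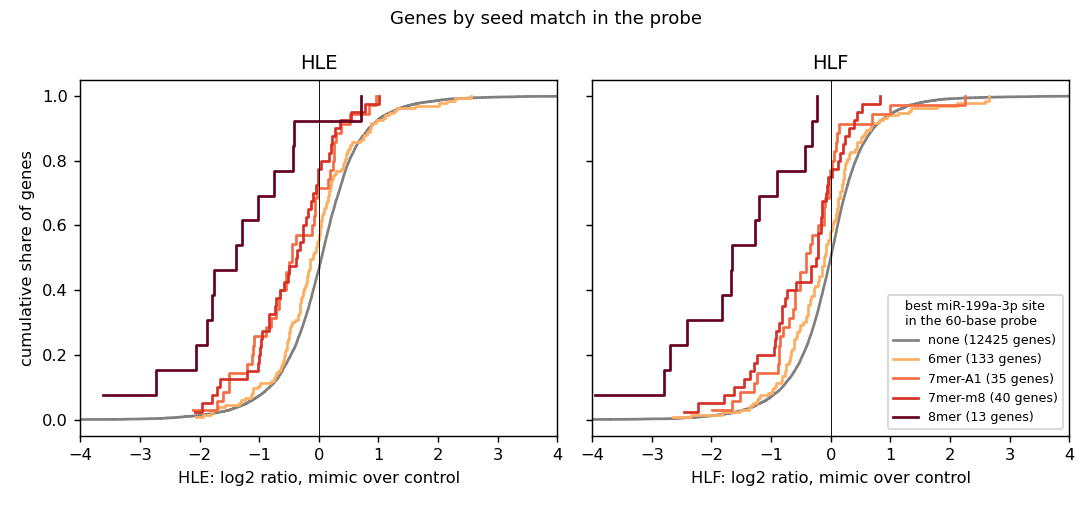
Cumulative share of genes (vertical axis) by log2 ratio of mimic over control (horizontal axis) in HLE and HLF, each from 1 array per group, with 1 curve for each kind of best miR-199a-3p match in the probe. The curve of the 13 genes with the 8-base match lies farthest to the left, with medians that differ by -1.44 and -1.65 from those of the 12425 genes without a match.

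Within HLE alone, 1207 genes were at least 2-fold lower after the mimic and 1626 at least 2-fold higher, with no test because each group holds 1 array. KRT86, a hair keratin, was 25.2-fold lower in HLE (log2 ratio -4.66, against -1.97 in HLF), and PLIN4, a lipid-droplet protein, was at least 7.27-fold lower in HLE and 2.19-fold in HLF. C11orf86 was at least 21.5-fold lower in HLE, and its other probe gave -2.18 in HLE and -0.18 in HLF. KRTAP5-9, one of a family of near-identical copies, and CD84 were at least 37.1-fold and 6.64-fold lower, but the other probe of CD84, not well above background on any array, gave 0.72 in HLE. Besides MMP3, the highest ratios included those of DBX1 (at least 214-fold), CCDC30 (log2 ratio 5.61, against 2.47 in HLF) and C9orf152 (at least 10.68-fold). KRTAP5-9, CD84, DBX1, CCDC30 and C9orf152 lay on the array beside another spot with an outlying difference between the lines.

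In HLF alone, 1149 genes were at least 2-fold lower and 1369 at least 2-fold higher, again with no test. Besides ELF3, the lowest ratios were those of FAS-AS1, an antisense transcript (at least 20.5-fold), DTX1 (at least 14.5-fold), NCF1, which has near-identical copies (at least 13.6-fold), and the NADPH oxidase NOX4 (at least 5.47-fold). Besides MMP3, the highest ratios were those of FAM229B (log2 ratio 12.30, against -0.27 in HLE), FHIP2A (11.72), TFF3 (at least 13.7-fold) and the keratin-associated KRTAP4-9 (at least 11.96-fold). The other probe of FHIP2A gave -0.65 in HLE and -0.09 in HLF. With clustered outlying spots left out another probe stood for NOX4 and for TFF3, not well above background in HLF, and the log2 ratio in HLF reversed to 1.67 and -0.86. Of these 10 genes, 7 lay beside another outlying spot: FAS-AS1, DTX1, NCF1, NOX4, FAM229B, FHIP2A and TFF3. None of the 30 genes named over both lines did. They were chosen for ratios of 1 sign in both lines, so this says little about faults of their spots.

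**Figure D4:**
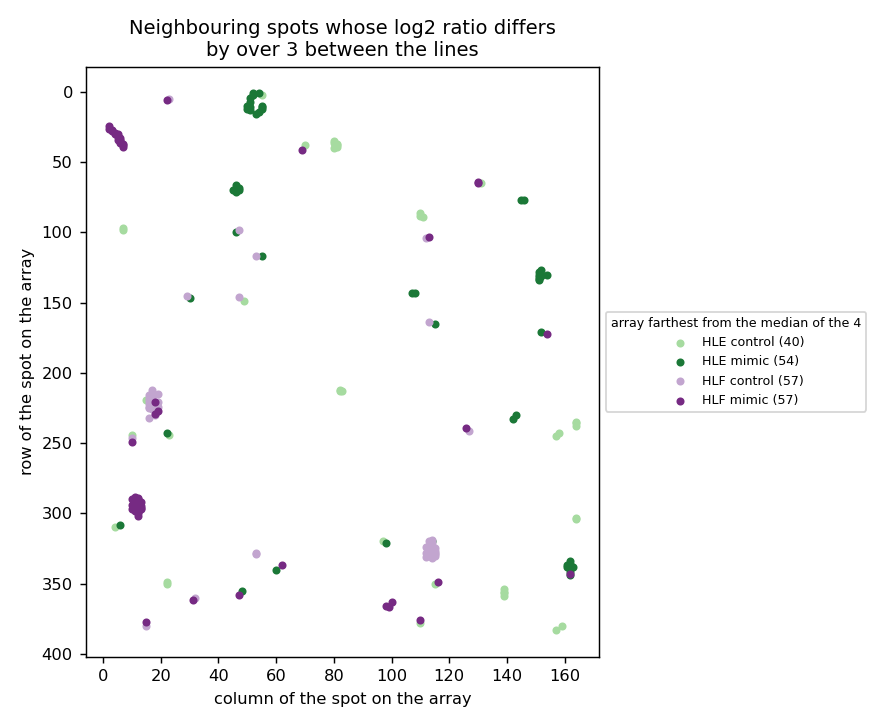
Row (vertical axis) and column (horizontal axis) on the array of the spots whose log2 ratio differed by over 3 between the lines and that lay beside another such spot, coloured by the array whose value was farthest from the median of the 4. The groups of neighbouring spots mostly share 1 colour, with 40 spots farthest on HLE control, 54 on HLE mimic, 57 on HLF control and 57 on HLF mimic. These are the 208 of 209 such spots whose probes were kept in the analysis.

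Few genes changed at least 2-fold with the mimic in opposite directions in the 2 lines. In all, 43 genes were at least 2-fold changed in opposite directions (13 lower in HLE and higher in HLF, 30 the reverse), against 196 for independent lists, and 18 among genes well above background on all 4 arrays. A technical shift shared by the mimic arrays could also lower the count of opposite genes. IL11, a cytokine, had log2 ratios of -0.86 in HLE and 4.37 in HLF. GPER1, a G-protein-coupled estrogen receptor, was 4.01-fold higher in HLE and at least 2.78-fold lower in HLF, and another probe gave 1.43 and -0.83, while 2 further probes, neither well above background in HLF, averaged 1.01 and 0.06. SYPL2 was at least 2.14-fold higher in HLE and at least 2.17-fold lower in HLF. The genes with the largest differences also included C11orf86 and several that lay beside another outlying spot: HECW2, NOX4, FAM229B, FHIP2A and ADAMTS14. The difference between the lines could not be tested, since 4 arrays leave no residual degree of freedom for it.

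The lines were also compared with each other, as a background to the mimic effect. IL13RA2, a decoy receptor of interleukin 13 (NM_000640), was at least 465-fold lower in HLF than in HLE with control, where its HLF signal was not well above background, and 398-fold lower with mimic (limma adjusted p = 0.0152). LHX1, a developmental transcription factor, was 369-fold lower in HLF with control and at least 146-fold lower with mimic. COL1A2 was 79.5-fold lower with control and at least 43.8-fold lower with mimic, and SMO, the transducer of Hedgehog signals, 75.5-fold and at least 44.5-fold. SPECC1, well above background on all arrays, had a mean log2 ratio of HLF over HLE of -7.33 ± 0.39 (SD of the 2 treatments) and MAL2 -6.38 ± 0.13, and PRXL2A and PXDNL were lower in HLF too. AJAP1, an adherens junction protein (NM_018836), was higher in HLF with 7.21 under control and 7.56 under mimic (mean 7.38 ± 0.25, limma adjusted p = 0.0116). ANK3, an ankyrin, had a mean of 7.97 ± 1.78, SLC16A3, a lactate transporter, 6.77 ± 0.44, and SRGN, a proteoglycan of secretory granules, was at least 77.7-fold higher in HLF with control and 75.2-fold higher with mimic. CUL9, SLC25A21, WDR90 and TUBA3C, whose copy is uncertain, were higher in HLF too. The limma adjusted p of these 16 genes lay between 0.0116 and 0.0254, and for those with a bound it rests on dim signals. By limma, 850 genes were lower in HLF and 997 higher at an adjusted p under 0.05, of which 828 and 949 differed at least 2-fold. These p-values rest on how alike the line difference was under control and mimic, not on replicate arrays of a line. With no block for treatment 58 genes passed, and with a modelled background and quantile scaling 3927.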

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

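All tests of explanations in this part were chosen after the results were seen.

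In 3 genes described here the ratios of mimic over control, as computed, were at least 2-fold in opposite directions in the single arrays of the lines. This difference between the lines was not tested. The log2 ratio in HLF minus that in HLE was 7.90 for ADAMTS14, a procollagen protease, whose lower value in HLE is only bounded at 1.57-fold. It was -5.71 for GPER1, for which another probe pointed the same ways (1.43 in HLE and -0.83 in HLF) but 2 probes not well above background in HLF averaged 1.01 and 0.06, and -4.06 for SYPL2. Because 1 to 2 of the 4 values behind each of these differences lay near background, their size is uncertain.

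ADAMTS14 belongs to a wider pattern: of 526 spots whose log2 ratio differed by over 3 between the lines, 209 lay beside another such spot on the array. Permuting the spot positions 1000 times gave at most 105, so local artifacts of the array surface are a candidate explanation for the neighbouring spots. Other probes of the same genes differed in the direction of the spot by a median of 0.16 (26 genes), where the spots themselves differed by 3.48. Probes that were themselves outlying had been left out of this comparison. Probes sharing a difference over 3 could thus not enter the median, and it does not decide against a response to the mimic in 1 line. For outlying spots that lay alone, such as those of GPER1 and SYPL2, the other probes, chosen in the same way, differed by a median of 0.86 (13 genes), too wide a range to decide. For these a response in 1 line and a fault of single spots cannot be told apart with 1 array per group.

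Probes for E1A spike-in RNA, which the comparisons did not use, were brighter on the mimic arrays by 0.33 ± 0.11 in HLE and 0.12 ± 0.08 in HLF (log2, SD over 8 probes). The 75th percentile of the gene signals moved the other way, by -0.67 and -0.42. A dimmer hybridization or scan of the whole mimic array would lower the spike-ins too, if equal amounts of them went in. Their mean difference of 0.23 over the lines argues against it only on that condition, which was not measured. Scaled to the spike-ins, the median of all genes was -0.71 over the lines (-0.91 in HLE, -0.50 in HLF). This may reflect less messenger RNA per amount of total RNA after the mimic, or less total RNA or more spike-in RNA in the labelling, and these cannot be told apart because the amounts that went in were not measured here.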

How the results depend on the processing

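Every count below rests on 4 arrays, and probes near background limit it: the mimic arrays had the lower 75th percentile, so that scaling alone raises the ratios of probes at background. Settings with spike-in scaling, without clustered spots or with 16 added in the model over both lines, and all alternatives for the opposite genes, were chosen after seeing the data. Except where the setting itself tests fewer genes or moves a threshold, the cause was not tested.

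The count of 0 genes past 0.05 for the mimic by limma stayed at 0 with quantile normalization, median centring, no filter, the mean of probes, the series table and no block for the line. It became 2508 with a modelled background and quantile scaling, 2022 with genes above background on all 4 arrays, 3380 with an eBayes trend, 2960 with 16 added, 6266 with spike-in scaling (5939 lower) and 378 without clustered spots. The modelled background gave 334 genes lower and 240 higher in both lines, 684 lower and 632 higher in HLE, 509 lower and 514 higher in HLF, 3927 genes between HLF and HLE, 3 opposite genes and a seed difference of -0.18. Spike-in scaling gave 2813 lower and 136 higher in both lines, 7740 lower and 293 higher in HLE, 3372 lower and 508 higher in HLF, and 1 list past 0.05. Median centring gave 1012 lower and 428 higher in both lines, and 1996 lower and 969 higher in HLE. No filter on dim probes gave 1273 higher in both lines, 1930 lower and 4680 higher in HLE, 1907 lower and 3528 higher in HLF, 236 opposite genes and r = 0.415 across genes. Genes above background on all 4 arrays gave 3065 between HLF and HLE and 18 opposite genes. A threshold of 1.5-fold gave 1578 lower and 1909 higher in both lines, and 3-fold gave 188 and 202. The addition of 16 gave 720 lower in HLF, no block for treatment 58 genes between HLF and HLE, and quantile normalization 2 lists. The seed difference was -0.18 with the mean of probes and -0.60 for 7-base and 8-base matches alone.

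The 642 lower genes all stayed at least 2-fold lower in both lines with quantile scaling, and 328 with the modelled background. Median and spike-in scaling lower every ratio of a line by a constant, so all 642 had to stay. Of the 700 higher genes, 575 stayed with quantile scaling and 238 with the modelled background. The constants left 428 of them with median and 136 with spike-in scaling. Of 747 recomputed values of named genes, 580 kept direction and call, 136 gained a call, 27 moved and 4 reversed. The 4 reversed without clustered spots, where another probe stands for the gene: CD84 in HLE at 0.72, and in HLF NOX4 at 1.67, FHIP2A at -0.0937 and TFF3 at -0.86. Matches in coding regions and untranslated regions were not run for want of sequence.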

Other observations

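The tests and gene families in this part were chosen after seeing the data.

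Among 144 families of genes that share a symbol stem and have at least 10 tested members, 3 lay beyond the 1st or 99th percentile of random lists in both lines. Genes with the stem RPL (50 genes), that of large ribosomal subunit proteins, had a median log2 ratio of 0.36 in HLE and 0.27 in HLF. Of these, 41 were higher in both lines, and the medians were 0.27 and 0.23 above the median of all genes. Spike-in scaling, which moves all genes alike, gives -0.64 and -0.27, and relative to all genes the family was at 0.03 and 0.03 with quantile normalization and at -0.06 and -0.04 with no filter on dim probes. The LSM family of RNA-binding proteins (13 genes) had 0.44 and 0.43 (-0.56 and -0.11 with spike-in scaling), which is 0.35 and 0.39 above all genes under both scalings, but 0.00 and 0.11 with no filter on dim probes. The transmembrane proteins named TMEM (163 genes) had -0.04 and -0.08, or -0.14 and -0.12 relative to all genes. With no filter on dim probes these were 0.09 and 0.09, or -0.35 and -0.23 relative to all genes. Genes with the stem RPS (39 genes), that of small ribosomal subunit proteins, had 0.36 in HLE and 0.11 in HLF. A stem is read from the leading letters only, so genes of other function, such as the RPS6K kinases, can count under it. Relative to all genes the RPS medians were 0.27 and 0.07, and the HLF median was -0.16 with quantile normalization. Spike-in scaling gives -0.64 and -0.44.

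Among the genes whose probe held the 8-base miR-199a-3p match, FAM234B had a log2 ratio of -1.76 ± 0.16, MMAB -1.74 ± 0.08, NDUFA12, a subunit of respiratory complex I, -1.33 ± 0.09 and TSPAN6 -1.24 ± 0.06. TWNK had -0.82 ± 0.11, CUL1 -0.43 ± 0.00, IMP3 -0.32 ± 0.13 and MDGA2 0.20 ± 0.72. The SD is that of the 2 lines.

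The lower ratios of genes with a miR-199a-3p match were followed up as a hypothesis, that the mimic lowers transcripts through its seed. Genes with the miR-196a-3p heptamer had a median that differed by -0.0157 from that of genes without a match, against -0.60 for the miR-199a-3p heptamer, which argues against a mimic of miR-196a-3p sequence. The base composition of the probes is argued against as well: among 424 heptamers of the same bases that share no run of 5 bases with it, the lowest z was -3.66, against -7.78 for ACTACTG. Of those that overlap it, CTACTGA, itself a seed match, had -7.12 and GACTACT -4.47. The heptamer ranked 1 of 11013 from the lowest in each line, which is consistent with lowering guided by the miR-199a-3p seed. Whether the matched transcripts are direct targets, and what a match outside the probe adds, stays open.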
